A study of Mus musculus with 2 samples.

How the data were processed

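RNA-seq libraries of 2 patient-derived xenograft tumors were compared, 1 from a primary and 1 from a metastatic gastroenteropancreatic neuroendocrine tumor, both grown in athymic nude mice. The sample titles share a code, but whether both came from 1 patient is not stated in the labels. Tumors had been dissociated with a kit for mouse tumors and RNA extracted from the tumor cell pellets, per the labels. The labels give mouse as the organism, and the submitters' processing notes name the human genome build GRCh38.

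Values were analysed as the FPKM deposited by the authors, in 1 table of 62573 rows with a column for each library. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.7.6a and Cufflinks 2.2.1, with no role or order. The annotation, the filters and the treatment of mouse reads are not given in the sources used here. The table holds no counts, so read depth is unknown and no counting interval is given. Low values carry some trace of depth. Of 6509 rows above 0 and below 1 FPKM in both libraries, 41.9% had a ratio of whole numbers up to 5 within a tolerance of 0.01%, against 0.123%, 0.676% and 0.415% when 1 library was multiplied by 0.95, 1.05 and 1.1. Multiplying by 0.8, 0.9 and 1.2, which turns some whole-number ratios into others, gave 23.2%, 3.76% and 12.9%. The share was highest without multiplication, as it would be if 1 fragment were worth about the same FPKM in both columns. An exact 0 can be a failed estimate, since LDHA, RPL7A and RPS25 were listed at 0 in both libraries.

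Rows with the same label were summed. Of all rows, 1734 name several symbols because overlapping genes were merged into 1 locus. Such a row was counted for a gene only where its other symbols were clone names, short RNAs or antisense RNAs, which left 820 merged loci and 12991 single genes among 13811 entries with at least 1 FPKM in at least 1 library. The log2 ratio was log2((metastatic + 1)/(primary + 1)), with a pseudocount of 1 FPKM and no rescaling.

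With 1 library per group there was no test and no p-value. Genes were counted as higher or lower at a 2-fold difference. For 40 gene lists fixed before the data were examined, the median log2 ratio over expressed members was computed for every list with an expressed member. Lists of at least 6 expressed members were given a 95% binomial interval of the median. Smaller lists were given the range of their members, which is not a 95% interval. For lists of at least 2 expressed members, the percentile of the median was taken among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. The percentile was repeated over 20 other random draws, and the side of the 2.5 and 97.5 limits differed between draws for 1 list, the polycomb genes. A further 12 lists were chosen after the data were examined.

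Named genes followed a rule fixed before the data were examined. It took the 15 genes with the largest positive and the 15 with the largest negative log2 ratio among genes of at least 10 FPKM in a library, leaving out short RNAs, clones, pseudogenes and immune receptor segments. It also took up to 4 members of each list with the largest absolute log2 ratio, and always EZH2, CHGA, SYP, MKI67 and SSTR2. Some genes that the rule takes are not reported here. VEGFA, EGLN1, JUN, HSPH1, CTRB1, CTRC, LUM, PECAM1, CDH5 and VWF in the results were chosen after their values were seen. HES4, HES6, HEY2, HEYL, B2M, ERAP1 and CD74 were also chosen after their values were seen. So were the genes named in the additional observations.

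Transcript length and GC content came from mouse transcripts of the same symbol, which covered 86.5% of 10801 expressed genes with a usable symbol; human transcripts were not used here. The procedure was tested on simulated data of 13811 genes with 200 changed. A 2-fold threshold recovered 80% of genes changed by 1.5 log2 units and 100% of those changed by 3, and 7.85% of unchanged genes passed it. The changed genes had a mean of at least 10 FPKM, and the noise was set from the ratios between these 2 libraries. These rates describe the simulation and not the error of the data, and changes of low genes were not simulated. Of 400 simulated lists without a shift 3.75% fell outside percentiles 2.5 to 97.5, and 100% of 100 lists shifted by 1 log2 unit lay above 97.5. Genes of the simulated lists were drawn independently from the pool that gave the random lists. A small share outside the limits was thus built in, and lists of genes that vary together were not covered.

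The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5 FPKM, no filter and a filter of 5 FPKM, a 4-fold threshold, and 4 scalings. The scalings were to a sum of 1000000, by the median ratio, by the 75th percentile, and to a sum of 1000000 without short, non-polyadenylated and mitochondrial genes. Added later were the highest in place of the sum of rows with 1 label, removal of the trend with length or GC content, random lists matched on length, and percentiles recomputed under each setting. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.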

Results

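RNA was sequenced from 2 patient-derived xenograft tumors, which are human tumors kept growing in immunodeficient mice. Both were gastroenteropancreatic neuroendocrine tumors carried in athymic nude mice. One library came from a primary tumor grown in the flank and one from a metastatic tumor grown in the peritoneal cavity. Each group held 1 library, so no difference between the groups had a replicate check, and no test was run. The location of the graft and the origin of the tumor differed together, and the labels do not say whether both tumors came from 1 patient, although the sample titles share a code. Values were FPKM, a measure that divides fragment numbers by transcript length and by a total of mapped fragments. They summed to 784987 in the primary and 885319 in the metastatic library. Low values often had whole-number ratios, as if 1 fragment were worth about the same FPKM in both columns. Whether each column was divided by the total of its own library is thus open. The values without rescaling may carry a difference in depth. The read depth behind these values is unknown. Log2 ratios below are metastatic over primary on the log2(FPKM + 1) scale, which understates differences of low genes.

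The comparison asked which genes differed between the primary and the metastatic xenograft. The genes furthest lower in the metastatic tumor included the transcription factor genes FOSB and FOS, the hypoxia response genes EGLN3 and CA9, and the collagen gene COL3A1. Those furthest higher included CCDC9B, MMP1, CASC19, IL33 and NTS. Of 13811 expressed genes and loci, 1273 were at least 2-fold higher and 1291 at least 2-fold lower in the metastatic tumor. The median log2 ratio was 0.03. With each library rescaled to the same sum, the median was -0.13 and the counts were 1029 higher and 1813 lower, so 36.2% of these genes were higher in place of 49.6%. With short, non-polyadenylated and mitochondrial genes left out before rescaling, the median was -0.12 and 36.4% were higher. At a 4-fold threshold 165 were higher and 259 lower, a share of 38.9% higher. Across genes, which are not independent replicates, the libraries correlated with a Pearson coefficient of 0.917 and a Spearman coefficient of 0.905.

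**Figure D1:**
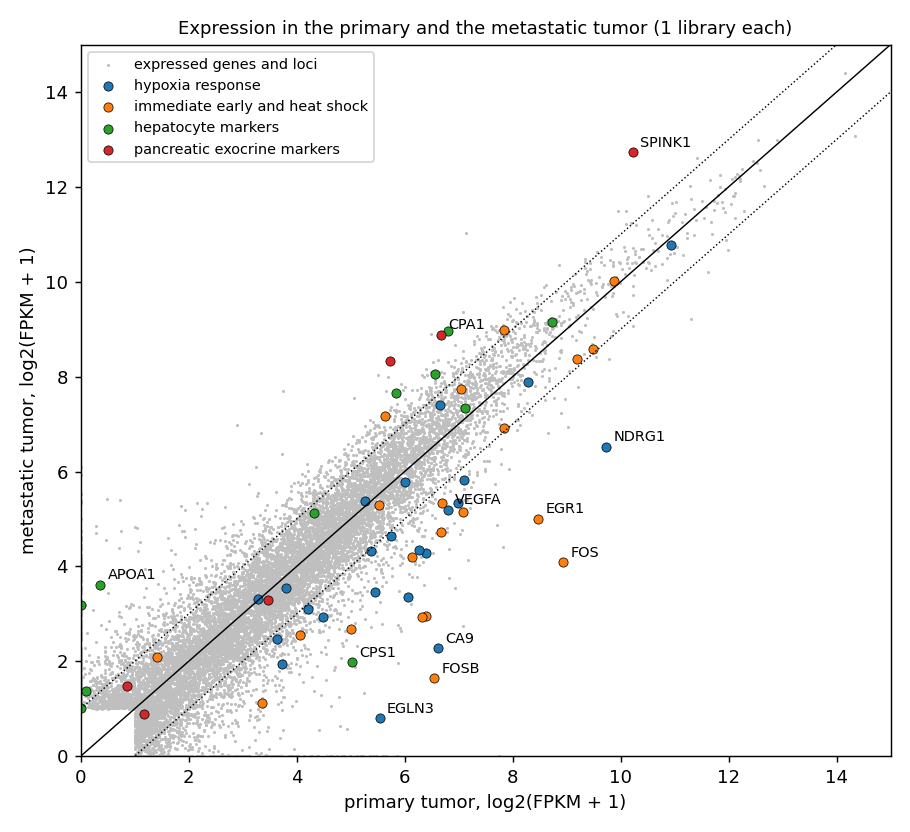
Expression of each expressed gene or locus in the primary tumor (horizontal axis) and the metastatic tumor (vertical axis), both as log2(FPKM + 1), with 1 library each. Colored points are members of 4 gene lists, the solid line marks equal values and the dotted lines a 2-fold difference; 16 of the 23 expressed hypoxia response genes lie below the lower dotted line.

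Among genes lower in the metastatic tumor, the AP-1 factor FOSB stood at 92.6 FPKM in the primary and 2.12 in the metastatic tumor, a log2 ratio of -4.91. FOS stood at 490 and 16.1 FPKM, and EGR1 at 354 and 31.1. EGLN3, an oxygen-dependent prolyl hydroxylase, stood at 45.4 and 0.741 FPKM, and CA9, a membrane carbonic anhydrase, at 97.7 and 3.83. NDUFA4L2 stood at 135 and 5.72 FPKM, and PCK1, an enzyme of gluconeogenesis, at 29.6 and 0.481. The imprinted gene RTL1 stood at 24.0 and 0.0106 FPKM, and the homeobox gene IRX3 at 57.5 and 2.90. SLCO4A1 had 36.9 and 1.54 FPKM, ADGRL2 20.4 and 0.466, and RERG 14.5 and 0.113. CRNDE and OCLM stood at 12 and 11.6 FPKM in the primary tumor and were listed at 0 in the metastatic tumor. COL3A1, a fibrillar collagen, stood at 23.9 and 1.07 FPKM.

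Among genes higher in the metastatic tumor, CCDC9B stood at 0.405 FPKM in the primary and 41.9 in the metastatic tumor, a log2 ratio of 4.93. The interstitial collagenase MMP1 stood at 0.667 and 41.3 FPKM, and PLAU, the urokinase plasminogen activator, at 9.11 and 111. The peptide neurotensin, encoded by NTS, stood at 140 and 2078 FPKM. The cytokine IL33 stood at 0.377 and 22.6 FPKM and EREG, a ligand of the EGF receptor, at 1.09 and 19.1. The noncoding RNA CASC19 stood at 6.43 and 126 FPKM. HPD stood at 1.0 and 27.6 FPKM, CPB2 at 1.13 and 21.8, ORM1 at 12.5 and 206 and ORM2 at 1.0504 and 27.2. The trypsinogen PRSS2 stood at 0.222 and 27.7 FPKM. ORM1, ORM2 and PRSS2 have near-identical copies, so their single values are uncertain. OSBPL1A had 0.684 and 26 FPKM, B3GNT8 0.644 and 19.9, and the zinc finger gene ZNF813 2.64 and 37.5.

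**Figure D2:**
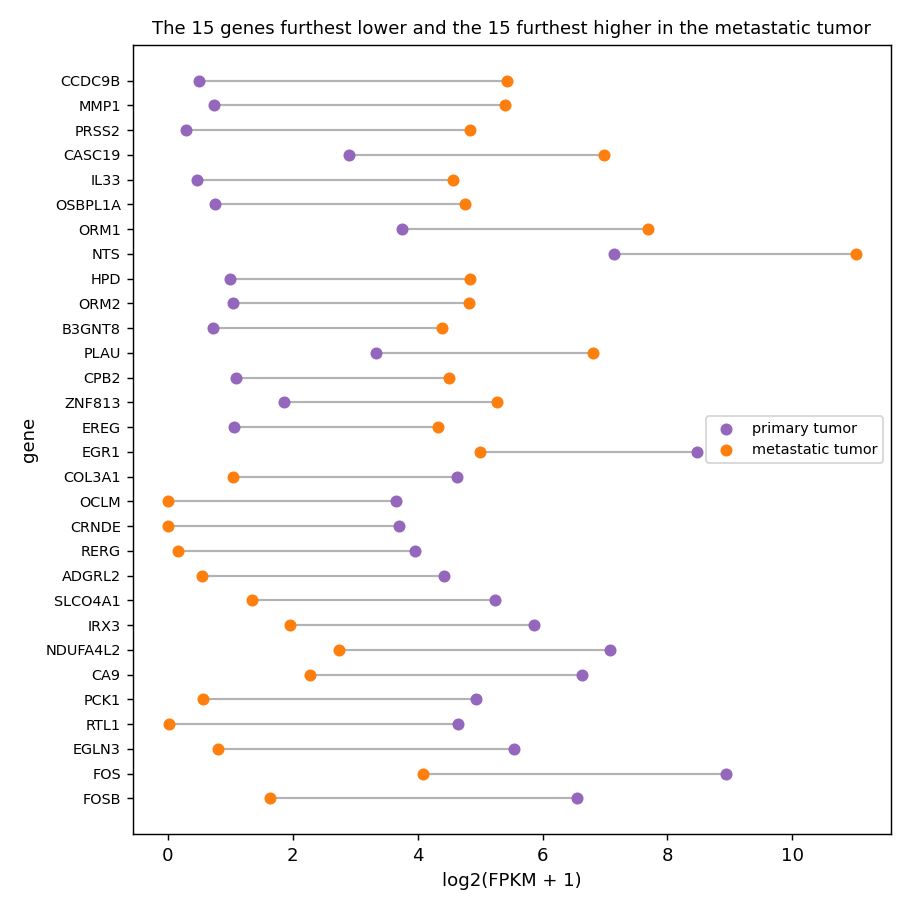
The 15 genes with the most negative and the 15 with the most positive log2 ratio among genes of at least 10 FPKM in a library, with log2(FPKM + 1) on the horizontal axis. Each point is 1 library, so no error can be drawn; NTS reached 2078 FPKM in the metastatic tumor, and FOS 490 in the primary tumor.

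Genes of the hypoxia response were lower in the metastatic tumor. Of 23 expressed members, 16 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.28 (95% binomial interval of the median across members -1.92 to -0.39). Of 10000 random lists matched on expression, 0 had a lower median, which describes these libraries and is no test of the conditions. NDRG1 stood at 849 FPKM in the primary and 91.2 in the metastatic tumor, the glucose transporter SLC2A3 at 66.2 and 9.31, and the angiogenic factor VEGFA at 110 and 35.8. EGLN1, at 99.5 and 169 FPKM, went the other way. Glycolysis enzymes had a median of -0.89, with 6 of 15 expressed members at least 2-fold lower and 0 higher, and 0 of 10000 random lists lay lower. ALDOC stood at 73.9 and 12.7 FPKM, the lactate transporter SLC16A3 at 45.4 and 8.54, SLC2A1 at 83.6 and 18.5 and PFKP at 109 and 25.4. The hypoxia and glycolysis lists share SLC2A1, HK2 and ENO1. LDHA, a gene of most cells, was listed at 0 in both libraries, so an exact 0 can be a failed estimate.

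Nuclear genes of oxidative phosphorylation had a median of 0.55, with 3 of 21 at least 2-fold higher and 0 lower, at percentile 91.3 of the random lists. COX6C stood at 260 and 804 FPKM, NDUFA1 at 209 and 490, ATP5F1A at 308 and 622 and COX7A2 at 691 and 1356. Short transcripts ran higher in the metastatic tumor, with a Spearman coefficient of -0.20 between length and log2 ratio across 9348 genes, and random lists matched on length as well put this list at percentile 75.

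The list of immediate early genes, which respond quickly to growth factors and to handling, and heat shock genes stood lower in the metastatic tumor. It had 21 expressed members, of which 12 were at least 2-fold lower and 2 higher. Its median was -1.5, and 0 of 10000 random lists lay lower. A split made after the values were seen gave 16 immediate early genes with a median of -1.94, 12 of them at least 2-fold lower and 0 higher, and 5 heat shock genes with a median of 0.70, 2 of them at least 2-fold higher and 0 lower. ATF3 stood at 83.5 FPKM in the primary and 6.76 in the metastatic tumor, and JUN at 102 and 39.5. HSPH1, a heat shock protein, stood at 49.0 and 143.

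Neuroendocrine genes were mixed. Of 13 expressed genes of the secretory granule, 2 were at least 2-fold higher and 2 lower, with a median of -0.30 at percentile 8.24. With a filter of 5 FPKM the median was 0.66 at percentile 95.7. The prohormone convertase PCSK1 stood at 19.9 FPKM in the primary and 2.74 in the metastatic tumor, and the granin SCG2 at 2.62 and 0.340. UCHL1 stood at 225 and 705 FPKM and DDC, which makes dopamine and serotonin, at 48.1 and 103. SYP, encoding synaptophysin, was low in both libraries, at 1.63 and 1.96 FPKM. CHGA, encoding chromogranin A, was listed at 0 in both libraries. Lineage transcription factors had a median of -0.08 over 15 genes, with 3 lower and 0 higher, at percentile 42.4. INSM1 stood at 3.54 and 0.271 FPKM, CDX2 at 8.30 and 3.42, SOX9 at 25.7 and 11.9 and ONECUT1 at 4.02 and 1.65. Neuronal axon and synapse genes had a median of -1.05 over 7 genes at percentile 0.26, with 4 lower and 1 higher; the percentile was 2.75 without the length trend and 50.2 without the filter on low values. NEFM stood at 5.35 and 25.2 FPKM, DPYSL3 at 21.2 and 8.60, STMN3 at 4.43 and 1.06 and NEFH at 2.09 and 0.446.

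Peptide hormones went both ways, with 2 of 6 higher, 3 lower, a median of -0.90 and percentile 1.24. The more abundant members were the higher ones. GAL, encoding galanin, stood at 45.0 and 121 FPKM beside NTS, while GHRL stood at 1.53 and 0.0379 and ADM at 11.5 and 4.52. With a filter of 5 FPKM the median was 1.41 at percentile 99.7. The percentile was 5.94 after rescaling to the same sum and 50.2 without a filter. Somatostatin receptors and other clinical targets had a median of 0.31 over 16 genes, with 4 lower and 0 higher, at percentile 90.4. PIM1 stood at 82.1 and 26.3 FPKM, GPC3 at 75.6 and 27.0, PTK2 at 69.9 and 29.8 and SSTR1 at 1.57 and 0.262. SSTR2 was reported only as a locus merged with COG1, at 21.9 and 34.3 FPKM. Genes recurrently altered in neuroendocrine tumors had a median of -0.04 over 21 genes, with 1 lower and 0 higher, at percentile 20.9. ATRX stood at 39.8 and 19.4 FPKM, CCNE1 at 14.1 and 27.6, CDKN1B at 36.9 and 23.6 and VHL at 21.8 and 15.5.

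The histone methyltransferase EZH2 stood at 20.7 FPKM in the primary and 27.1 in the metastatic tumor, a log2 ratio of 0.37. Polycomb genes as a list had a median of -0.30 over 26 genes, with 1 lower and 0 higher. The list also holds KDM6A and KDM6B, which encode histone demethylases and not polycomb subunits. PHC1 stood at 11.8 and 2.47 FPKM, KDM6A at 17.5 and 8.47, AEBP2 at 24.0 and 12.5 and PCGF5 at 2.75 and 5.36. The percentile of this list was 2.48, at the 2.5 limit. It ran from 2.30 to 2.81 over 20 other random draws and fell outside the limit in 7 of them, so it gave no call that held.

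Cell cycle genes had a median of 0.29 over 34 genes, with 5 higher and 0 lower, at percentile 86.1. The replication factors MCM3, at 20.7 and 51.6 FPKM, and CDC45, at 15.8 and 37.5, were among the higher ones, with CCNE2 at 1.5 and 4.83 and E2F1 at 4.59 and 11.7. The proliferation marker MKI67 stood at 24.5 and 18.2 FPKM. Mesenchymal genes had a median of -0.56 over 16 genes, with 2 lower and 0 higher, at percentile 0.05. Fibroblast markers, of which this list holds 0, were also lower, with a median of -1.59 and 7 of 10 at least 2-fold lower. MMP2 stood at 5.26 and 0.599 FPKM, LOX at 5.30 and 1.54, ZEB1 at 9.53 and 4.65 and TGFBI at 55.1 and 90.8. Epithelial adhesion and keratin genes had a median of 0.37 over 14 genes, with 3 higher and 2 lower, at percentile 88.2. CLDN4 stood at 2.30 and 10.6 FPKM, ESRP2 at 2.76 and 7.49, ELF3 at 62.1 and 17.1 and KRT7 at 146 and 61.2. Matrix proteases and their inhibitors went both ways, with 5 of 16 higher and 3 lower, a median of -0.18 and percentile 10.3. The inhibitor TIMP1 stood at 989 and 2862 FPKM.

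Unfolded protein response genes had a median of 0.57 over 20 genes at percentile 98.1, with 5 higher and 2 lower. Without the GC trend the percentile was 96.0, within the limit. CHAC1 stood at 0.429 and 9.89 FPKM and ASNS, asparagine synthetase, at 63.2 and 218, while PPP1R15A stood at 60.3 and 17.5. Antigen processing genes had a median of 0.89 over 7 genes at percentile 98.7, with 3 higher and 0 lower. Of the 15 members, 6 were under 1 FPKM in both libraries and 2 stood only in merged loci. The 3 higher ones were NLRC5, CALR and PDIA3. The transactivator NLRC5 stood at 1.49 and 7.54 FPKM, and the chaperones CALR, PDIA3 and CANX at 1451 and 3581, 140 and 320, and 86.9 and 162. B2M, ERAP1 and CD74 were within 2-fold, at 92.2 and 118, 6.81 and 5.87, and 1.51 and 1.45 FPKM. The percentile of antigen processing genes was 92.1 after rescaling to the same sum, 93.4 by the upper quartile and 43.6 without a filter. Inflammatory genes had a median of -0.47 over 14 genes at percentile 1.18, with 2 lower and 0 higher. CXCL1 stood at 5.94 and 1.73 FPKM, NFKBIA at 55.2 and 25.1, CXCL2 at 16.6 and 8.29 and LIF at 106 and 56.3. Interferon response genes had a median of -0.12 over 18 genes at percentile 33.6, with 1 higher and 3 lower. BST2 stood at 6.79 and 1.32 FPKM, OAS1 at 18.5 and 7.86, IFI44 at 1.58 and 0.230 and ISG15 at 9.49 and 20.5. Apoptosis regulators had a median of 0.21 over 21 genes at percentile 78.6, with 3 higher and 2 lower. BCL2A1 stood at 0.657 and 4.74 FPKM, BID at 27.5 and 62.7, CASP8 at 49.7 and 20.9 and MCL1 at 387 and 182.

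**Figure D3:**
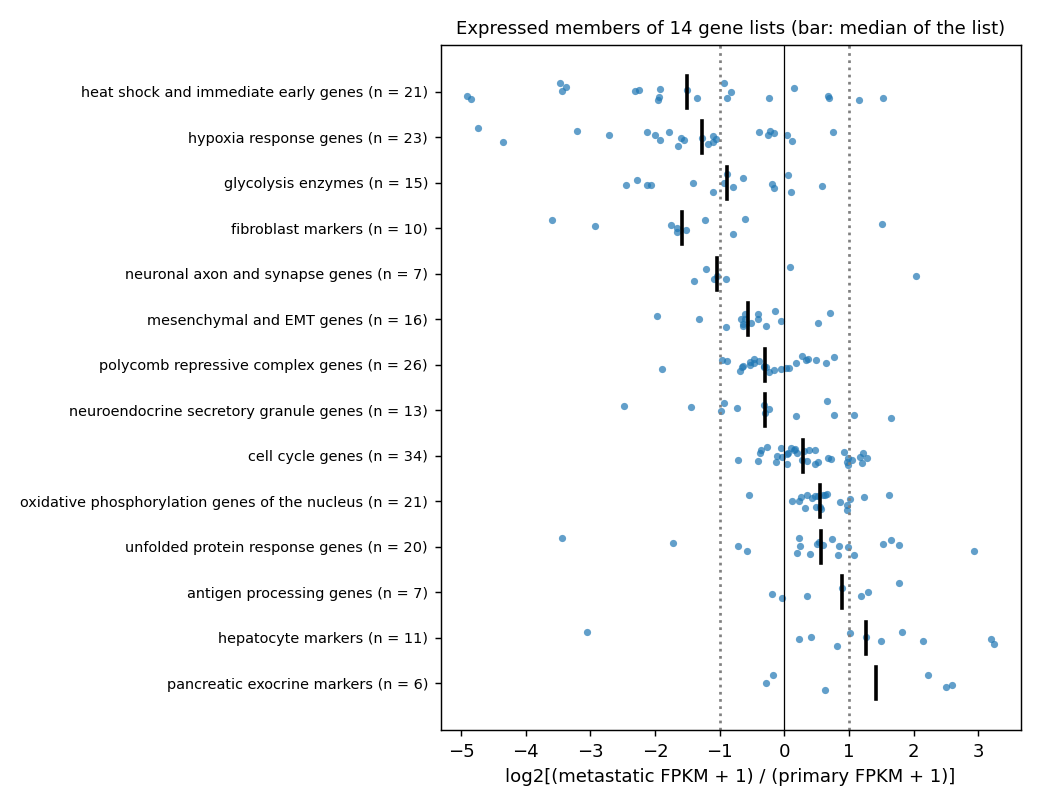
Log2 ratio, metastatic over primary tumor, of each expressed member of 14 gene lists; every point is a gene, the bar is the median of the list and dotted lines mark a 2-fold difference. Medians run from -1.59 for fibroblast markers to 1.42 for pancreatic exocrine markers, and most lists hold members on both sides of 0.

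Notch pathway genes had a median of -0.27 over 16 genes at percentile 7.21, with 4 lower and 0 higher. The Notch effectors HES1 and HEY1 stood at 129 and 24.5 FPKM and at 149 and 50.4, DLK1 at 3977 and 1883 and MAML2 at 1.11 and 0.0548. Other HES and HEY genes went both ways. HEY2 stood at 16.3 and 26.7 FPKM, HEYL at 5.16 and 8.98, HES6 at 22.4 and 42.0 and HES4 at 17.3 and 12.4. Wnt target genes had a median of -0.65 over 9 genes at percentile 0.70, or 50.2 without a filter, with 3 lower and 0 higher. APCDD1 stood at 3.45 and 0.316 FPKM and LGR5 at 3.21 and 1.16. TGF-beta and BMP response genes had a median of -0.15 over 17 genes at percentile 17.2, with 4 lower and 0 higher. BMP7 stood at 4.56 and 0.159 FPKM, ID1 at 8.93 and 3.05, TGFB3 at 6.73 and 2.24 and BAMBI at 31.4 and 14.8. Stemness-associated genes had a median of -0.40 over 11 genes at percentile 2.67, with 4 lower and 0 higher. KLF4 stood at 36.1 and 9.50 FPKM, SALL4 at 18.5 and 5.23, ALDH1A3 at 2.10 and 0.279 and LIN28B at 1.35 and 0.0562. Cholesterol synthesis genes had a median of -0.26 over 19 genes at percentile 0.29, with 2 lower and 0 higher. HMGCS1 stood at 82.0 and 38.2 FPKM, STARD4 at 25.2 and 11.8 and LSS at 7.52 and 3.30.

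Pancreatic exocrine markers were higher in the metastatic tumor or within 2-fold. Of 6 expressed pancreatic exocrine markers, 3 were at least 2-fold higher and 0 lower, with a median of 1.42 (interval -0.28 to 2.59) at percentile 99.98, or 43.6 without a filter. The trypsin inhibitor SPINK1 stood at 1198 FPKM in the primary and 6825 in the metastatic tumor and the carboxypeptidase CPA1 at 101 and 473. PNLIP, pancreatic lipase, stood at 0.823 and 1.81 FPKM, and CTRB1 and CTRC at 10.2 and 8.86 and at 1.25 and 0.847. Of 11 expressed hepatocyte markers, 7 were higher and 1 lower, with a median of 1.27, and 0 of 10000 random lists lay higher. The fibrinogen chain FGB stood at 111 and 499 FPKM and the apolipoprotein APOA1 at 0.289 and 11.2. APOA2 was listed at 0 in the primary tumor and stood at 8.16 FPKM in the metastatic tumor, while CPS1, of the urea cycle, stood at 31.7 and 2.96.

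Genes used as markers of stromal cells differed between the libraries. Fibroblast markers had a median of -1.59 over 10 genes, with 7 lower and 1 higher, and 0 of 10000 random lists lay lower. COL1A2 stood at 474 and 149 FPKM, COL1A1 at 12.6 and 3.02 and FSTL1 at 10.004 and 0.444. Of the 16 fibroblast markers listed alone, 6 were under 1 FPKM in both libraries, with LUM at 0 and 0.0859. Smooth muscle and pericyte markers had a median of 0.88 over 9 genes at percentile 99.87, or 82.1 without a filter, with 3 higher and 0 lower. MYL9 stood at 12.2 and 81.5 FPKM, DES at 1.40 and 7.82, CNN1 at 0.707 and 3.41 and MCAM at 3.25 and 7.01. Of 13 endothelial markers 3 were expressed, with a median of -1.48 at percentile 1.03. This call was lost with a filter of 5 FPKM (percentile 4.27), after rescaling to the same sum (2.82, or 31.0 without short, non-polyadenylated and mitochondrial genes) and without a filter (54.4). EGFL7 stood at 19.1 and 1.58 FPKM, CLDN5 at 5.73 and 1.41 and ESAM at 1.55 and 1.18. Among those not expressed, PECAM1 stood at 0.237 and 0.0833 FPKM, CDH5 at 0.152 and 0.0144 and VWF at 0.259 and 0.505. Whether stromal or tumor cells gave the values of these lists was not tested. How reads of mouse host cells were treated is not given in the sources used here, so their share in these values is open.

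Few markers of other cells were expressed. Macrophage markers had a median of -0.19 over 3 genes at percentile 46.7, with LYZ at 2.72 and 12 FPKM, CSF1R at 1.06 and 0.243 and LAPTM5 at 1.12 and 0.853. A filter of 5 FPKM left LYZ alone, with a log2 ratio of 1.80 and no percentile. The lymphocyte list had 1 expressed gene, CD3D, at 1.72 and 1.93 FPKM and a log2 ratio of 0.11. Mesothelial markers had a median of 0.16 over 2 genes at percentile 62.0, with WT1 at 0.0477 and 2.65 FPKM and UPK3B at 1.78 FPKM and listed at 0. Adipocyte markers had a median of -0.18 over 3 genes at percentile 41.9, with CIDEC at 1.64 and 3.28 FPKM, AQP7 at 1.62 and 0.920 and LIPE at 2.88 and 2.43. Erythroid markers had a median of 0.54 over 3 genes at percentile 84.7, with HBB at 33.5 and 96.0 FPKM, HBD at 3.19 and 1.60 and HBA1 at 2.10 and 3.49. Schwann and glial markers had a median of -0.56 over 3 genes at percentile 16.9, with MBP at 14.1 and 5.28 FPKM and PMP22 at 8.49 and 5.43. Of 10 skeletal muscle markers 0 were expressed.

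Cytosolic ribosomal protein genes were close to equal, with a median of -0.03 over 35 genes and 0 past 2-fold. Their percentile was 0.04, as random lists of similar abundance had higher medians. RPS23 stood at 2277 and 1505 FPKM, RPL23 at 1084 and 1615 and RPL38 at 688 and 1020. Replication-dependent histone genes had a median of -0.77 over 11 genes at percentile 0.07, with 1 higher and 2 lower. HIST1H4C stood at 1.27 and 9.24 FPKM, HIST1H2BC at 20.4 and 8.63, HIST1H1C at 315 and 152 and HIST1H2BK at 112 and 60.3. Mitochondrially encoded genes were mostly reported as merged loci, and the 2 listed alone had a median of 0.39 at percentile 52.8. MT-CYB stood at 2732 and 6279 FPKM and MT-ND6 at 102 and 75.4. Of 38 lists with a percentile, 14 lay in the lowest 2.5% and 5 in the highest 2.5% of the random lists. The polycomb list was among the 14, and 5% of the lists would make 1.9. Among these lists, the interval of the median spanned 0 for hormone, polycomb, cholesterol, Wnt, inflammatory, neuronal and ribosomal genes. It also did for antigen processing, smooth muscle and pancreatic exocrine genes. For cholesterol genes it ran from -0.76 to 0.36 and for smooth muscle markers from -0.68 to 1.87. An extreme percentile thus did not always go with a median clear of 0. Genes of a list vary together, so the percentiles rank the lists within this pair of libraries only.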

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

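The trends with length and GC content, length-matched random lists, the highest-row setting and all percentiles under other settings were chosen after the results were seen; the other alternatives were planned. No paired analysis was possible because each group held 1 library and no test was run. The counts of higher and lower genes stayed within 1.5 times under the 4 other scalings and both other pseudocounts; of 165 named genes, 42 moved by over 1.5 times with a pseudocount of 0.1 and 14 with 0.5, and 0 of those past 2-fold changed direction. The cause was not tested except where the construction shows it. With a pseudocount of 0.1 the Pearson coefficient was 0.855, the median of peptide hormones -1.47 and of the lymphocyte list 0.16, and the percentiles were 1.09 for stemness and 3.29 for polycomb genes; with 0.5 the lymphocyte value was 0.13 and these percentiles 2.11 and 3.38. Without a filter, where most added genes are near 0, the median of all genes was 0.0, the Pearson coefficient 0.971, and 11 list medians were 0.0: hormone, clinical target, epithelial, Wnt, antigen processing, neuronal, endothelial, lymphocyte, mesothelial, pancreatic exocrine and Schwann genes; fibroblast markers had -0.70 and smooth muscle markers 0.13. Percentiles were then 54.4 for endothelial, 50.2 for Wnt, 50.2 for neuronal and 50.2 for hormone genes, 43.6 for antigen processing and 43.6 for pancreatic exocrine genes, 82.1 for smooth muscle, 0.87 for granule, 1.29 for lineage and 1.70 for stemness genes. With a filter of 5 FPKM, which leaves fewer genes, 859 genes were lower, the median of all genes was 0.082 that of peptide hormones 1.41, at percentile 99.7, that of granule genes 0.66, at 95.7, and that of macrophage markers 1.80; percentiles were 4.27 for endothelial, 2.48 for stemness and 19.7 for polycomb genes. A 4-fold threshold gave 165 higher and 259 lower. Rescaling to 1000000 gave medians of -0.13 for all genes, -0.73 for mesenchymal, -0.59 for adipocyte and -0.54 for lymphocyte genes, and percentiles of 2.82 for endothelial, 92.1 for antigen processing, 2.29 for TGF-beta and 5.94 for hormone genes. Without short, non-polyadenylated and mitochondrial genes these were -0.12, -0.73, -0.60 and -0.55, and 31.0, 93.9, 1.95 and 5.29. The median ratio gave -0.0016 for all genes and 0.083 for lymphocytes. The upper quartile gave -0.052, with 0.048 for lymphocytes, -0.50 for adipocytes, and percentiles of 2.65 for polycomb and 93.4 for antigen processing genes. Without the length trend, oxidative phosphorylation had a median of 0.34, lymphocytes -0.091 and neuronal genes percentile 2.75; without the GC trend, lymphocytes had 0.095, and percentiles were 96.0 for unfolded protein and 8.04 for polycomb genes. Polycomb genes stood at 2.96 with the highest row and 2.83 with length matching. Read depth is unknown, so low genes carry an error that cannot be given.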

Other observations

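The lists of the first 2 paragraphs, the list of acinar transcription factors and further enzymes, the test of library scale, the test of heat shock genes and the test of acinar enzymes were chosen after the results were seen. Aminoacyl-tRNA synthetases, which load amino acids onto transfer RNA, had a median log2 ratio of 0.94 over 19 genes, with 8 at least 2-fold higher and 1 lower, and MARS stood at 97.8 FPKM in the primary and 464 in the metastatic tumor. Targets of the stress factor ATF4 outside the unfolded protein list had a median of 0.87 over 15 genes, with 7 higher and 1 lower. NUPR1 stood at 7.70 and 52.3 FPKM and GDF15 at 135 and 656. Proteasome subunits had a median of 0.80 over 28 genes, with 7 higher and 0 lower, and PSMD1 stood at 240 and 639 FPKM. Mitochondrial ribosomal proteins had a median of 0.73 over 62 genes with 16 higher and 0 lower, and mitochondrial import genes 0.91 over 19 with 7 higher and 0 lower. EGF family genes went both ways, with a median of 0.55 over 5 genes, AREG at 8.52 and 67.6 FPKM and ERBB2 at 10.4 and 3.36.

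Metallothioneins, which bind zinc and copper, were lower, with a median of -1.39 over 10 genes and 6 at least 2-fold lower; MT1G stood at 2526 and 591 FPKM, and these genes resemble each other closely. Collagens had a median of -0.84 over 21 genes, 10 of them lower and 0 higher. Of these 10, 5 are also fibroblast markers, a list with a median of -1.59. Laminins, also of the matrix, had -0.16 over 11 genes with 2 lower. Insulin-like growth factor binding proteins had a median of -1.21 over 6 genes with 4 lower, and IGFBP4 stood at 33.8 and 4.0 FPKM. Imprinted genes had a median of -0.73 over 8 genes with 3 lower. The merged locus of IGF2 and INS stood at 20789 and 8637 FPKM and the MEG3 locus at 1203 and 539.

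Hypoxia response genes had a median of -1.28. Under the 4 other scalings the highest median was -1.32, but a scaling moves all genes about alike and could change it little. The median of all genes was 0.03, and -0.13 at the lowest under these scalings. A shift of this size does not account for -1.28. Removal of the trend with transcript length left -1.40, and removal of the trend with GC content left -1.24. Both trends were small. Across 10 groups of genes by length the median log2 ratio ran only from -0.25 to 0.22, and by GC content from -0.05 to 0.14. Removing them could therefore move the list little, and neither trend as the whole cause accounts for its median. The primary or metastatic origin of the tumor may differ in oxygen supply, as may the flank and the peritoneal cavity, and with 1 library per group these cannot be told apart.

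Pancreatic exocrine genes were present in both tumors, including the flank graft, where CPA1 stood at 101 FPKM. RNA of normal pancreatic acinar cells could be a source. Of 8 enzyme genes of the exocrine list that were listed alone, 1 was at 0 in both libraries, and the median over the other 7 of their highest value was 1.81 FPKM, with 3 at 10 FPKM or more. CPA1 was high while PRSS1 did not pass 0.159 FPKM and CPB1 0.0125. Some of these genes have close copies among which reads can be lost, and the treatment of mouse reads is not known, so the enzyme levels leave this source open. In a list of acinar transcription factors and further enzymes, with a median of 0.17 over 10 genes, 3 higher and 1 lower, PTF1A stood at 25.4 and 50.9 FPKM and REG1A at 3140 and 1177.

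Immediate early genes had a median of -1.94 over 16 genes. A handling stress that induces them together with heat shock genes, if stronger in the primary tumor, would raise both there. The 5 expressed heat shock genes instead had a median of 0.70, with 2 at least 2-fold higher and 0 lower. This median was at least 0.59 under the 4 other scalings. HSPA8 was close to equal, at 0.15 and down to -0.024 after rescaling to the same sum. The list was split after these values were seen, and levels before handling are not known, so the heat shock genes do not decide it. Removal of the trend with transcript length left the immediate early genes at -1.94. A handling difference that induces immediate early genes alone, such as the time to dissociation, may also account for them. Since 0 handling times are recorded for the libraries, neither handling cause can be told apart from the origin of the tumor or the location of the graft.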
